A study of Homo sapiens with 4 samples.

How the data were processed

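The series holds RNA sequencing of HEK293T cells, a human embryonic kidney line, after transfection of an expression vector for SF3B1, the largest subunit of the SF3b complex that binds the intron branch point as part of the U2 snRNP. There were 4 libraries, 1 for each vector: the wild-type protein (WT) and the substitutions R625H, K666T and K700E. Per the labels, 1000 ng of plasmid was used for R625H and for K666T and 2000 ng for K700E; the amount for WT is not given in the sources used here. Per the labels, poly(A) RNA was made into stranded libraries and read as 100-bp pairs. With 1 library per group, no difference has a replicate check, and intervals cover counting error only.

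The authors deposited raw read counts per gene and raw read counts per splice junction for each library. Per the submitters' processing notes, STAR 2.5.3a and HTSeq were used with hg19/GRCh37; the role of HTSeq, the annotation release and other settings are not given in the sources used here. The gene files hold unstranded and strand-specific counts, and column 4, the counts on the strand opposite to read 1, was used because the labels name a stranded kit; the other strand held 5.79, 5.74, 5.72 and 5.97% of the stranded gene reads in WT, R625H, K666T and K700E. The 4 rows of each gene file that name no gene were left out of library sizes: unmapped pairs (8.84, 16.46, 17.31 and 15.17% of pairs in WT, R625H, K666T and K700E), multimapping pairs (4.4, 4.11, 4.01 and 4.14%), pairs in no feature (5.23, 5.01, 5.19 and 5.87%) and ambiguous pairs (3.43, 3.15, 3.04 and 3.27%). The junction files list the position, motif, uniquely mapped reads, multi-mapped reads and, as a deposited value in nt, the longest overhang of a spliced alignment, at most 50 nt. Of 57820 gene IDs, 51996 were paired with an entry of a gene name table, 39538 of them with a symbol that is not itself an ID.

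The junction files mark between 99.84 and 99.86% of junctions as annotated, so that column could not tell annotated from unannotated sites. Annotation status was instead taken by matching the lengths and order of introns and exons of each gene in GENCODE release 29 (GRCh38) to the hg19 junctions of the same chromosome, requiring at least 2 introns to fall together; only the hg19 positions of the files are printed. Of 18193 protein-coding genes with at least 2 introns, 15706 were matched, against 26 genes of any type when all were searched on a wrong chromosome. This departs from the plan made before the data were examined. Gene names of junctions come from this match, and junctions outside matched genes are called unnamed.

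An acceptor pair is made of 2 acceptors joined to the same donor, the upstream one 10 to 30 nt before the downstream one, with at least 20 uniquely mapped reads on both together in each of the 4 libraries and canonical motifs only. The upstream share is the percent of those reads on the upstream acceptor. Positions give the last base of the intron on hg19. Each mutant library was compared with WT, and the mutant libraries with each other, by a two-sided Fisher's exact test per pair with Benjamini-Hochberg adjustment. A call needed an adjusted p under 0.05 and a difference of at least 10 percentage points; such a test compares libraries, not conditions. "Rose" and "fell" are used of shares that passed it. The same test was run on 6 control classes: acceptor pairs 3 to 9 and 31 to 100 nt apart, donor pairs 3 to 9, 10 to 30 and 31 to 100 nt apart, and cassette exons of 10 to 500 nt. Cassette exons with both ends annotated were also counted apart, a set chosen after the data were examined. Many tested pairs had a site with no read in at least 1 library, so all counts were repeated on pairs with both acceptors read in all 4 libraries, and on those with an annotated downstream acceptor; both sets were added after the data were examined. The pooled upstream share sums reads over pairs with an unannotated upstream and an annotated downstream acceptor, with Wilson 95% intervals. Mutants were also compared on pairs called in the third mutant, with intervals from 2000 bootstrap draws over pairs.

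Gene expression was compared as the log2 ratio of counts scaled to library size (CPM) with a prior count of 10, without a test, for 14847 genes with a CPM of at least 1 in at least 1 library. Genes at least 2-fold apart were counted. The median of each of 23 gene lists fixed before the data were examined was placed as a percentile among 10000 random lists of the same size, matched on mean expression; a list is said to stand apart when its median lay outside the central 95%. Random draws could take members of the list itself. They were bounded at the most abundant gene, so for lists of very abundant genes they fell on few genes. The lists are genes known for altered acceptors in SF3B1-mutant cells, U2 snRNP and acceptor recognition, nonsense-mediated decay, heme synthesis and iron, serine and one-carbon metabolism, interferon response, NF-kB targets, integrated stress and unfolded protein response, heat shock, p53 targets, immediate early genes, MYC targets, cell cycle, replication-dependent histones, cholesterol synthesis, hypoxia and glycolysis, nuclear and mitochondrial respiratory chain genes, ribosomal proteins, and markers of melanocytes, blood cells, fibroblasts and HEK293T cells. RIGI, listed under its older symbol, and CCL5 were not joined to the interferon list, and 3 of the 16 histone symbols were found. Overlaps between mutants, which share the WT library, were set beside the overlap of independent lists, and covariances beside 20 simulations of unchanged libraries. Those simulations hold counting error only.

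Names were chosen by a rule written before the data were examined. For splicing it takes, for each mutant, the 10 largest rises and the 3 largest falls, every tested pair in the list of known genes, and the 5 largest differences between each pair of mutants. For expression it takes SF3B1; for each mutant the 6 highest and 6 lowest genes with at least 100 reads in 1 of the compared libraries; the 5 highest and 5 lowest of the genes at least 2-fold apart in all 3 mutants; and up to 4 members of each list that stands apart. Not every pair or gene the rule takes is printed. The same splicing rule was applied to both added sets, and names outside it are said to be so.

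On simulated data with 200 changed features, the pair test called 86, 88 and 98% of the shares raised by 15, 25 and 40 points in R625H, 88, 98 and 100% in K666T and 86, 94 and 98% in K700E. It called none of those raised by 5 points, which is under the limit of 10 points, and 0, 0 and 1 of 20565 unchanged pairs. The expression step put all genes multiplied by 4 or 0.25, all multiplied by 2.5 and 94, 98 and 98% of those multiplied by 0.4 past 2-fold, and no unchanged gene. Both simulations held counting error only. They do not show how often differences between libraries other than the vector give a call. Alternatives varied the read minimum, the limit in points, the distance window, the read type, the motifs, the overhang, the annotation, the depth, the scaling (TMM of edgeR 4.0.16, and size factors of DESeq2 1.42.0, both in R 4.3.3), the prior count, the CPM filter and the count column. Other steps used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6, Numba 0.67.0 and Matplotlib 3.10.9.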

Results

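Poly(A) RNA of HEK293T cells was sequenced after transfection of a vector for wild-type SF3B1 or for SF3B1 with the substitution R625H, K666T or K700E, with 1 library for each of the 4 vectors. The substitutions lie in the HEAT repeats of SF3B1, a core component of the U2 snRNP, where cancer-associated mutations cluster. Reads assigned to genes numbered 90939945 in WT, 82254731 in R625H, 86394759 in K666T and 83025588 in K700E. Uniquely mapped reads across splice junctions came to 72034388, 66015665, 68666760 and 71122502 in the same order. SF3B1 itself had 505.9 CPM in WT, 517.3 in R625H, 520.9 in K666T and 512.2 in K700E, log2 ratios to WT of 0.03, 0.04 and 0.02. Whether reads from the vector align to the gene was not tested, so these levels were not used to check the labels. There were no replicates, and the Wilson intervals given for shares cover counting error only.

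The comparison of each mutant with WT asked at which acceptors usage differed, and genes known for altered acceptors in SF3B1-mutant cells are given at the start. The upstream acceptor share of DPH5, an enzyme of diphthamide synthesis, rose from 0.14% in WT (95% interval 0.03 to 0.81) to 20.05% in R625H (16.29 to 24.44), 18.55% in K666T and 19.96% in K700E, at chromosome 1 position 101458311, 14 nt before the downstream acceptor of a coding exon. ENOSF1 (chromosome 18, 683396, 15 nt) rose from 3.69% to 43.68, 28.32 and 28.75% in R625H, K666T and K700E. TMEM14C, a mitochondrial protein needed for heme synthesis, rose from 6.64% to 35.63, 34.63 and 23.37% at an acceptor 14 nt upstream (chromosome 6, 10724788). ORAI2, a store-operated calcium channel, rose from 2.5% to 35.45, 38.46 and 28.28% at an acceptor of a 5' UTR exon (chromosome 7, 102076648, 23 nt). BRD9, a subunit of a SWI/SNF complex, rose from 51.85% of 27 reads to 85.58, 88.89 and 88.31% (chromosome 5, 869520, 10 nt).

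Other known genes rose in all 3 mutant libraries. The dynein light chain DYNLL1 (chromosome 12, 120934204) went from 7.59% to 31.7, 26.93 and 22.03%, and DLST, a subunit of the oxoglutarate dehydrogenase complex (chromosome 14, 75356580), from 1.33% to 26.21, 18.52 and 18.98%. The palmitoyltransferase gene ZDHHC16 reached 21.12, 19.08 and 18.99% from 3.27%, and TTI1, a partner of PI3K-related kinases, 27.0, 34.31 and 28.88% from 4.33%. MAP3K7, the kinase TAK1, rose from 8.91% to 23.4, 25.35 and 21.51%, PPP2R5A, a regulatory subunit of protein phosphatase 2A, from 0.74% to 14.69, 13.04 and 13.02%, and SEPTIN6 from 1.68% to 18.59, 14.17 and 20.54%. HINT2, whose reads overlap another gene and are uncertain, rose in R625H and K666T, to 19.94 and 16.67% from 2.97%, and stood at 12.7% in K700E, a difference below 10 points. At 1 of its 2 acceptor pairs, GAS8, a component of ciliary dynein regulation, rose in R625H from 3.85 to 32.48%, with 7.02% in K666T and 4.6% in K700E, and R625H differed from both. Its other pair had 54.55% of 33 reads in WT and 78.57, 77.78 and 77.27% in the mutant libraries, without a call. ZNF561 went the other way in all 3, from 91.26% to 57.14, 67.69 and 76.6%.

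**Figure D1:**
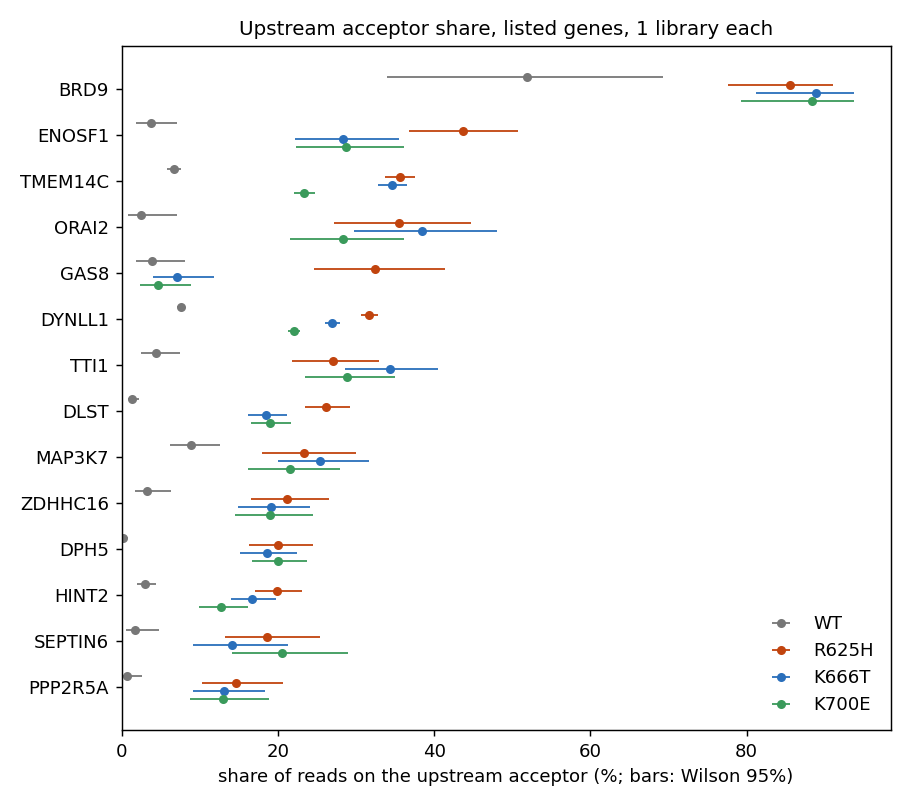
Percent of junction reads on the upstream acceptor (horizontal axis) in listed genes with a called rise, with 1 point per library and Wilson 95% intervals as bars. Pairs were first limited to called rises read in all 4 libraries with an annotated downstream acceptor. The pair with the most WT reads among these is drawn for each gene. Some genes have an uncalled pair with more WT reads, as DPH5 does. WT lies below the mutant libraries in most genes, as in DPH5 with 0.14% against 20.05% in R625H, while in GAS8 only R625H stands apart.

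Over the whole list, 82 pairs in 29 gene labels were tested. Of these, 15 rose in R625H, 14 in K666T and 13 in K700E, while 2, 1 and 2 fell; adjusted over the list alone, 16, 14 and 14 rose. The share of pairs that rose was 18.29, 17.07 and 15.85% in these genes against 1.38, 1.05 and 1.02% in all other genes. The list also held cassette exons: inclusion of a BRD9 exon known to truncate the reading frame (chromosome 5, 869359 to 869520) rose from 3.05% to 20.97, 16.49 and 17.22%, and a COASY exon, in the coenzyme A synthase gene, from 19.01% to 60.96, 62.5 and 53.67%. Inclusion of a short GAS8 exon (chromosome 16, 90097583 to 90097598) rose in all 3, from 7.41% to 31.17, 29.59 and 25.19%. This GAS8 exon starts at the upstream acceptor of the uncalled GAS8 pair above, and the BRD9 exon at that of the BRD9 pair. Exon and pair are thus not separate observations in these genes. An ABCC5 exon rose from 9.0% to 38.2% in R625H and 56.52% in K666T and had 15.96% in K700E. Inclusion also fell in listed genes. A DLST exon fell from 92.65% to 77.66, 81.29 and 79.67%, and another COASY exon from 87.37% to 76.03, 73.54 and 73.56%. Exons of TTI1, AP1G1 and GAS8 were among those that fell in some mutants only.

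Outside the list, the largest rises at acceptors read in all 4 libraries included CDK20, a cyclin-dependent kinase (chromosome 9, 90585561, 15 nt), from 6.45% of 31 reads to 73.47, 64.71 and 70.37%. GEN1, a Holliday junction resolvase (chromosome 2, 17941178, 17 nt), rose from 6.45% to 67.35, 80.21 and 69.29%, and the golgin gene GCC2 (chromosome 2, 109102954, 12 nt) from 0.76% to 54.97, 39.08 and 39.57%. SCAMP3, a membrane trafficking protein (chromosome 1, 155228704, 20 nt), rose from 36.84% to 84.31, 86.36 and 59.04%, CCDC66 from 17.92% to 62.42, 54.86 and 40.94%, and MFSD9 from 6.49% to 43.75, 33.75 and 47.41%. BCL2L1, an inhibitor of apoptosis, rose from 30.36% to 57.94, 64.83 and 59.35%. Among pairs read in all 4 libraries, the largest fall in R625H and K666T was in MTERF2, a mitochondrial transcription factor, from 83.78% to 28.09, 36.53 and 37.21% at a 5' UTR exon. RPL8, a ribosomal protein gene, fell from 34.27% to 0.87, 0.98 and 0.56%. In all, 46 pairs with both acceptors read in every library and an annotated downstream acceptor rose in all 3 mutants. NFYA, a CCAAT-binding factor (0.62% to 23.68, 16.2 and 17.22%), and BUB1B, a spindle checkpoint kinase (6.24% to 25.4, 20.25 and 16.45%), were among them and were picked after the values were seen.

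Across 20765 acceptor pairs 10 to 30 nt apart, the upstream share rose at 301, 231 and 224 pairs in R625H, K666T and K700E and fell at 130, 134 and 163. Among the 3965 pairs with both acceptors read in all 4 libraries, 146, 103 and 89 rose and 35, 26 and 36 fell. With an annotated downstream acceptor as well (2796 pairs), 123, 80 and 67 rose and 15, 7 and 15 fell. These rises had a median distance of 17, 15 and 17 nt, against 20 nt for the pairs tested. Of them, 113, 73 and 56 lay at coding exons, meaning exons with any coding part in some transcript. The pooled upstream share of pairs with an unannotated upstream acceptor was 0.132% in WT (0.131 to 0.134), 0.319% in R625H (0.316 to 0.322), 0.227% in K666T (0.225 to 0.229) and 0.238% in K700E (0.236 to 0.241), over 11550 pairs.

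**Figure D2:**
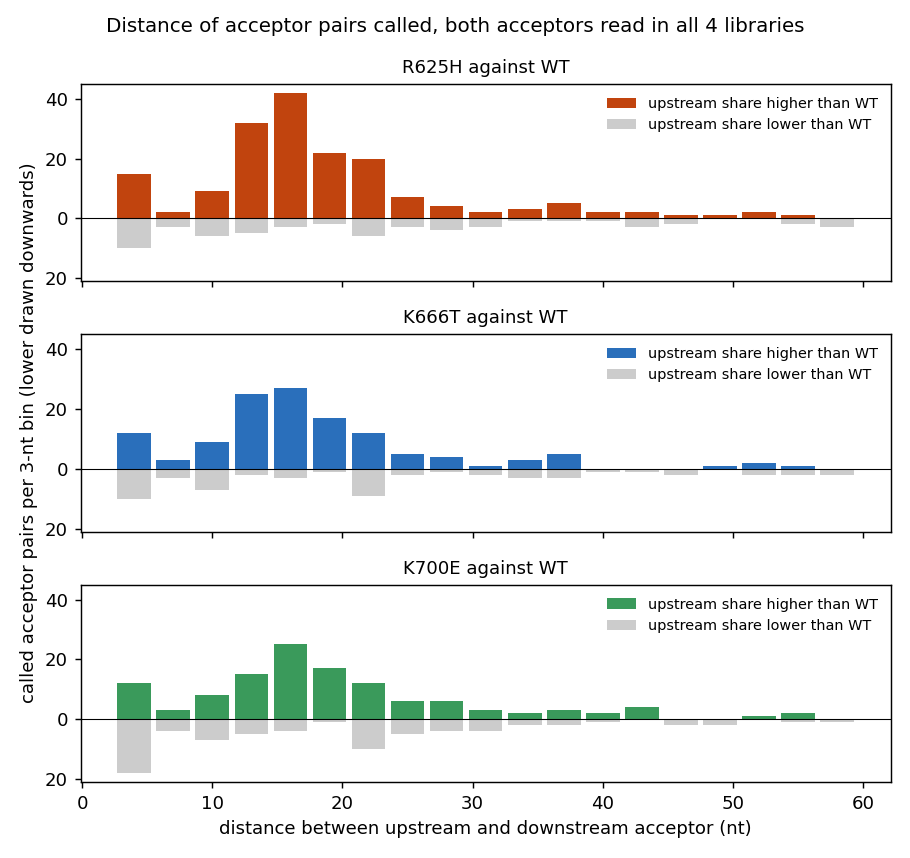
Number of called acceptor pairs per bin of 3 nt (vertical axis, falls drawn downwards) by the distance between both acceptors (horizontal axis, nt), for each mutant library against WT, over pairs read in all 4 libraries. The bin of 15 to 17 nt held the most rises, 42 in R625H, 27 in K666T and 25 in K700E of 650 tested pairs; that of 12 to 14 nt held 32, 25 and 15 of 436.

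The control classes were measured the same way. Of the acceptor pairs 3 to 9 nt apart read in all 4 libraries, 13, 15 and 16 rose and 10, 14 and 25 fell in R625H, K666T and K700E. At 31 to 100 nt, 45, 35 and 52 rose and 36, 32 and 38 fell, and donor pairs 10 to 30 nt apart gave 2, 4 and 6 rises and 4, 10 and 6 falls. Donor pairs 3 to 9 nt apart gave 1, 2 and 4 rises and 3, 0 and 3 falls, and those 31 to 100 nt apart 10, 16 and 36 rises and 9, 14 and 20 falls. In K700E, rises made up 71.2% of the calls of acceptor pairs 10 to 30 nt apart and 64.3% of those of donor pairs 31 to 100 nt apart. Before the limit to sites read in every library, these percentages were 57.9 and 60.2, so there K700E leaned no further than this control class. In the 6 classes together, before that limit, 577, 582 and 660 rose and 695, 876 and 1269 fell; cassette exons made up 227, 228 and 275 of these rises and 309, 476 and 861 of these falls. The pooled upstream share was also higher in some control classes. It was 0.387, 0.431, 0.504 and 0.584% in WT, R625H, K666T and K700E for donor pairs 10 to 30 nt apart and 0.632, 0.631, 0.740 and 0.832% for those 31 to 100 nt apart. For acceptor pairs 31 to 100 nt apart it was 0.0822, 0.105, 0.115 and 0.116%, and for those 3 to 9 nt apart 4.56, 4.16, 4.68 and 4.36%.

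**Figure D3:**
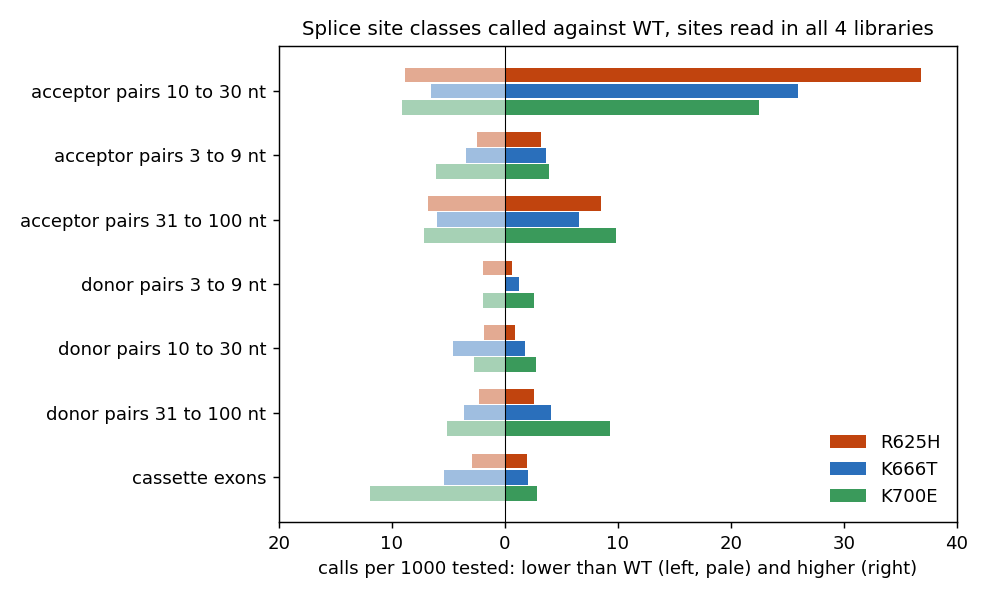
Calls per 1000 tested pairs or exons (horizontal axis, falls to the left in pale colours, rises to the right) for each class of splice site and each mutant library against WT, over sites read in all 4 libraries. Acceptor pairs 10 to 30 nt apart had 146, 103 and 89 rises, and cassette exons had 178, 332 and 733 falls, in R625H, K666T and K700E.

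Many of the largest called rises over all pairs sat at abundant transcripts with an acceptor that had no read in some library. HSP90B1, a chaperone of the endoplasmic reticulum (chromosome 12, 104336900), went from 0% of 165 reads in WT (upper 95% limit 2.28%) to 100, 74.51 and 57.89%. The malate dehydrogenase gene MDH2 (chromosome 7, 75689715) went from 14.29% to 100% in each mutant library, and H2AZ1, a histone variant gene, from 0 to 49.72, 100 and 100%. The nucleophosmin gene NPM1 (chromosome 5, 170817068) had 78.38% in R625H and 77.24% in K700E but 0% in WT and K666T, and EIF5A, a translation factor, 100% in K700E and 0% in the other 3 libraries. Of the rises, 160 in R625H, 129 in K666T and 136 in K700E were of this kind. CD81 and DDX1 were among the falls of this kind, each at 100% in WT and 0% in R625H.

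Cassette exons with both ends annotated (31766) changed mostly towards skipping, and most of all in K700E. Inclusion rose at 25, 33 and 42 exons in R625H, K666T and K700E, in 21, 30 and 41 genes. It fell at 41, 105 and 255 exons, in 35, 90 and 214 genes. Exons that share an end were each counted, as in ABCD4 and HDAC10. The mean change was -0.47, -0.64 and -0.98 points. An exon of PIK3IP1, an inhibitor of PI3-kinase (chromosome 22, 31685300 to 31685380), fell from 86.96% to 42.86% in K700E, with 54.55 and 65.38% in R625H and K666T, which were not called. An exon of LDHB, a lactate dehydrogenase subunit whose reads overlap another gene, fell from 63.16 to 22.22% in K700E (44.23 and 35.63%). In DCAF16, a substrate receptor of a ubiquitin ligase, inclusion fell from 89.08% to 54.81, 55.67 and 60.27%, and in HROB, a homologous recombination factor, it fell to 61.65% in K666T and 56.52% in K700E from 86.05%, with 73.39% in R625H. HDAC10, a deacetylase, fell from 91.67 to 60.38% in K700E, with 77.42% in R625H and 60% of 30 reads in K666T, not called. The lysine methyltransferase gene SETD6 fell from 75 to 41.18% in K700E, with 64.29 and 56.25% in R625H and K666T. An exon of MAGEA2B, a cancer-testis antigen with near-identical copies and so uncertain, rose from 50% to 93.88, 87.97 and 96.58%, and exons of NCOR1, a nuclear corepressor, and MYCBP2, a ubiquitin ligase, had called rises in K700E, from 29.79 to 56.1% and from 18.39 to 45%. R625H and K666T were near these, at 50.46 and 47.41% in NCOR1 and 37.5 and 39.02% in MYCBP2, without a call. Of the exons that fell in K666T and K700E, 45 fell in both, against 0.84 for independent lists. Part of the excess may come from the shared WT library and from exons that share an end.

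The title of the series names the position and the charge of the substitution as its question. The mutants were compared with each other, but their substitutions differ in position and in side chain at once, with 1 library each. Position and charge therefore cannot be told apart here. R625H exchanges arginine for histidine, K666T replaces a positive side chain by an uncharged one, and K700E by a negative one. Among pairs read in all 4 libraries with an annotated downstream acceptor, R625H stood above WT and both other mutants at 8. These included RHNO1, a DNA damage checkpoint factor (23.45% against 4.85 in K666T and 7.12 in K700E, 1.08 in WT), CCNYL1, a cyclin Y homologue (22.93 against 2.58 and 4.63%, 0.94 in WT), and COPS2, a COP9 signalosome subunit (15.3 against 4.55 and 2.34%, 0.42 in WT). In this set no pair stood so in K666T or in K700E. Without the annotation limit such pairs numbered 10, 4 and 4 in R625H, K666T and K700E, and over all pairs 42, 33 and 26. ENOSF1 was higher in R625H than in K666T over all pairs (adjusted p 0.0427) but missed the limit among pairs read in all 4 libraries with an annotated downstream acceptor (0.0606). TMEM14C was higher in R625H and in K666T than in K700E; SCAMP3 and UBL7, a ubiquitin-like protein (63.0 against 35.92%), were higher in K666T than in K700E. MYL6, a myosin light chain gene, had 66.67 and 67.53% in R625H and K666T and 23.81% in K700E, with 58.9% in WT.

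Over the pairs read in all 4 libraries with an annotated downstream acceptor, R625H was above K666T at 15 and below at 5, above K700E at 32 and below at 8, and K666T was above K700E at 13 and below at 2. Over all pairs the counts were 135 and 117, 168 and 112, and 150 and 125. On the 80 pairs chosen in K666T, the change from WT was greater in R625H than in K700E by a median of 5.92 points (bootstrap 95% interval 3.42 to 7.92). On the 67 pairs chosen in K700E, it was greater in R625H than in K666T by 2.32 points (0.72 to 4.77), and on the 123 chosen in R625H greater in K666T than in K700E by 2.3 points (0.78 to 3.17). Without the limit to those pairs, a set added after the data were examined, the 3 medians were 0 points (0 to 1.9, 0 to 1.0 and 0 to 0.32). The pooled share ordered K666T and K700E the other way, at 0.227 and 0.238%. Rises of R625H and K666T shared 68 pairs, those of R625H and K700E 54, and those of K666T and K700E 50, against 3.52, 2.95 and 1.92 for independent lists. The changes covaried by 29.54, 25.68 and 23.44 against 4.76, 4.65 and 4.67 in simulations of unchanged libraries, which hold counting error only. Part of the overlap may come from the shared WT library, and how much was not measured. The plasmid amount was 2000 ng for K700E and 1000 ng for R625H and K666T, so in comparisons with K700E the mutation cannot be separated from the amount.

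Interferon-response genes were the group that stood furthest from WT in gene expression. IFIT1, an antiviral RNA-binding protein, had 2703 reads in WT and 16801, 12230 and 98989 in R625H, K666T and K700E, and was higher by log2 2.78 (2.72 to 2.84, counting error), 2.25 (2.19 to 2.31) and 5.32 (5.27 to 5.38). RSAD2, the antiviral enzyme viperin, which is outside the fixed list, had 108 reads in WT against 1357, 913 and 15300, the highest log2 ratio of K700E at 7.14. The oligoadenylate synthetases OAS1 and OAS2 each had 28 reads in WT and reached 3014 and 4004 in K700E. IFNB1, the gene of interferon beta, had 8 reads in WT and 67, 57 and 362 in the mutant libraries, and the chemokine CXCL10 30 against 209, 180 and 1266. Of 23 list members measured, 18, 16 and 22 were at least 2-fold higher, and the list median was 2.39, 1.92 and 4.40, above all 10000 random lists in each library. IRF1, a transcription factor of the response, was higher by log2 0.46, 0.04 and 0.85. The RNA sensor RIGI, outside the joined list and named after its values were seen, was higher by 2.25, 1.84 and 4.29.

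**Figure D4:**
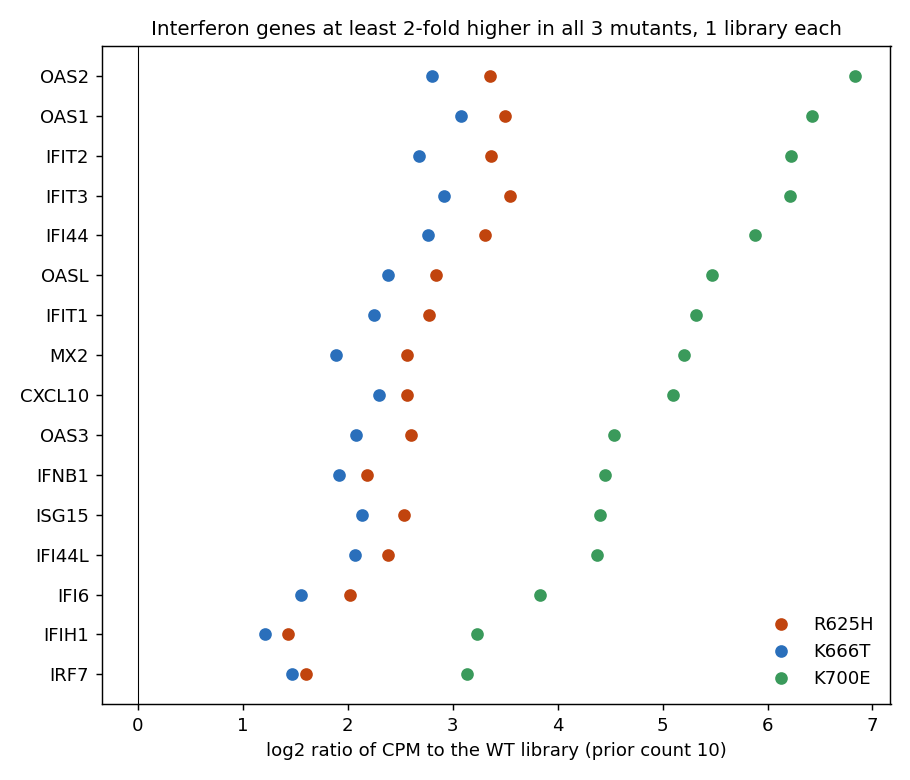
Log2 ratio of CPM to the WT library (horizontal axis, prior count 10) for the 16 genes of the interferon list at least 2-fold higher in all 3 mutant libraries, with 1 point per mutant library and no error bars, as there are no replicates. K700E lies to the right of the other mutant libraries in every gene, and R625H to the right of K666T, as in IFIT1 with 5.32, 2.78 and 2.25.

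Signalling and stress genes were higher in the mutant libraries by smaller amounts. Immediate early genes had medians of 0.48, 0.70 and 0.64 in R625H, K666T and K700E, led by the transcription factors EGR1 (1.18, 1.57 and 1.32) and FOS (1.10, 1.23 and 1.13). The NF-kB list had medians of 0.59, 0.16 and 0.26, with RELB, a subunit of NF-kB, higher by 1.33, 0.70 and 0.83 and TNFAIP3, its inhibitor A20, by 0.96, 0.53 and 0.71. In the list of the integrated stress and unfolded protein responses (0.21, 0.26 and 0.12), PPP1R15A, which directs dephosphorylation of eIF2 alpha, was higher by 1.05, 1.18 and 1.38, and DDIT3, the transcription factor CHOP, by 0.49, 0.80 and 0.81. The p53 list had medians of 0.22, 0.15 and 0.21, with PLK3 at 0.64, 0.59 and 0.70. Heat shock genes had medians of 0.09, 0.05 and 0.06, at percentiles 98.85, 94.38 and 90.79 of random lists. Among them BAG3 was at 0.38, 0.41 and 0.36, while HSPE1 was at least 2-fold lower in K700E.

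Splicing and decay genes were slightly higher. The U2 snRNP list had medians of 0.10, 0.12 and 0.14, with SUGP1, a branch point recognition partner of SF3B1, higher by 0.70, 0.77 and 0.90 and ZRSR2 by 0.17, 0.33 and 0.59. Nonsense-mediated decay factors and targets had medians of 0.09, 0.10 and 0.20. The decay-sensitive non-coding RNAs ZFAS1 (0.54, 0.44 and 0.44) and SNHG12 (0.52, 0.48 and 0.41) were higher. This list also holds the stress gene GADD45B, likewise higher, and ATF4, which is in the integrated stress list too. Its median is therefore not a measure of decay alone. MYC targets had medians of 0.09, 0.10 and 0.08, with the ribosome biogenesis gene RRP12 at 0.25, 0.30 and 0.37; the percentile of K700E, 97.92, was just outside the central 95%. FBL, a nucleolar methyltransferase, was higher in K700E by 0.67 and stood at -0.05 and -0.03 in R625H and K666T.

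The genes known for altered acceptors and several metabolic lists were lower. The known genes had list medians of -0.08, -0.07 and -0.09, the last inside the central 95% at a percentile of 2.99. DPH5 was at -0.63, -0.55 and -0.45, PPP2R5A at -0.63, -0.40 and -0.66, and MAP3K7 at -0.41, -0.27 and -0.35. The heme and iron list had medians of -0.07, -0.10 and -0.19, with GLRX5, a mitochondrial glutaredoxin, at -0.58 in K700E. The serine and one-carbon list had medians of -0.07, -0.09 and -0.06, led by PHGDH, the entry enzyme of serine synthesis, at -0.65, -0.58 and -0.40; in K700E the list lay inside the range of random lists, at a percentile of 10.93. Cholesterol synthesis had medians of -0.12, -0.20 and -0.15, with the sterol sensor INSIG1 at -0.34, -0.51 and -0.69 and SQLE at -0.23, -0.32 and -0.41. Hypoxia and glycolysis genes had medians of -0.18, -0.12 and -0.13, inside the range in K700E at 5.25, with PDK1 at -0.35, -0.19 and -0.27. Nuclear genes of the respiratory chain had -0.07, -0.10 and -0.15, with COX5A at -0.08, -0.19 and -0.81. Mitochondrially encoded genes had 0.08, -0.09 and -0.42, and MT-ATP6 was at 0.11, -0.07 and -0.71. Their percentiles of 99.89, 41.58 and 5.33 decide nothing. For the most abundant genes the random draws fell on few genes and could take list members.

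Cell cycle genes (0.01, 0.03 and -0.02), melanocyte markers (3 measured, 0.03, 0.08 and 0.00) and HEK293T markers (0.01, 0.05 and -0.06) lay inside the range of random lists. Ribosomal proteins (0.00, -0.06 and -0.07) did so too, but the limit of random draws among the most abundant genes applies to them as well. Fibroblast markers, 4 of them measured at low levels, had medians of -0.28, -0.34 and -0.38, with COL3A1 at 709, 508, 483 and 486 reads in WT, R625H, K666T and K700E. Of the blood cell markers and of the histone genes, 2 each passed the CPM filter, too few for a median; the 12 blood markers summed to 4.06, 3.64, 3.59 and 4.52 CPM.

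In total, 97, 103 and 194 genes were at least 2-fold higher in R625H, K666T and K700E and 4, 1 and 65 lower, with 66 higher in all 3, of which 16 were in the interferon list. Others among the 66, named after their values were seen, were FGF21, a stress-responsive hormone (1.39, 2.37 and 2.33), ITGAM, an integrin subunit (1.73, 1.55 and 1.60), and MAGEA2B, uncertain for its copies (2.55, 2.55 and 3.23). NPM1P6, a pseudogene of NPM1 whose reads may belong to its parent, was the gene lower in all 3 (-3.37, -3.17 and -4.13). The lowest genes of K700E were mostly such pseudogenes, RPL13AP25 (-2.07) and RPS15P4 (-1.66) among them; in R625H they included LMF1, a lipase maturation factor (-0.80), and in K666T C4orf48 (-0.82). Between mutants, 5 genes were higher and 5 lower in R625H than in K666T, 30 and 97 in R625H than in K700E, and 17 and 89 in K666T than in K700E. The genes higher in 2 mutants numbered 70 for R625H and K666T, 79 for R625H and K700E and 89 for K666T and K700E, against 0.67, 1.27 and 1.35 for independent lists. Log2 ratios covaried by 0.0506, 0.0751 and 0.0771 across genes, which are not replicates, against 0.0032 in simulations of unchanged libraries. The simulations hold counting error only. Neither they nor independent lists show how much of the overlap a difference of the WT library itself adds. Without the CPM filter 190, 211 and 392 genes were higher and 23, 15 and 135 lower; at a CPM of at least 5, 53, 49 and 93 were higher and 2, 1 and 23 lower.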

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

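The tests of the plasmid amount, of the extent of upstream acceptor use and of the overhang of reads were chosen after their results were seen. The share of read pairs left unmapped, a signal in data that the comparisons did not use, was 16.46% in R625H, 17.31% in K666T and 15.17% in K700E against 8.84% in WT. At 8 of the 2796 acceptor pairs read in all 4 libraries with an annotated downstream acceptor, R625H stood above WT and both other mutants in Fisher tests between libraries, adjusted over that set. K666T and K700E had 0 such pairs there; over all pairs the counts were 42, 33 and 26 in R625H, K666T and K700E. R625H exceeded the higher of the other mutants by 25.46 points in GAS8, 18.3 in CCNYL1, 16.8 in APPL2 and 16.33 in RHNO1. The margin was 12.03 points in SETD4, 10.91 in ARMH4, 10.85 in C1D and 10.75 in COPS2.

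Interferon-response genes were higher in all 3 mutant libraries and highest in K700E, whose list median exceeded the higher of the others by 2.0. Blood cells in the culture are argued against, as the summed CPM of their markers was 4.52 in K700E (4.07 to 5.0) and 4.06 in WT (3.65 to 4.49). The amount of plasmid and the mutation cannot be told apart, because the single library given 2000 ng is the K700E library and the amount for WT is not given in the sources used here. The extent of upstream acceptor use alone would put R625H highest, but its median lay below that of K700E (-2.0). Its pooled upstream share was the higher, 0.319% (0.3164 to 0.3224) against 0.238% (0.2355 to 0.2405). That is the outcome set as going against this explanation. The plasmid amount of K700E differed, and between the libraries given 1000 ng, R625H was above K666T in both measures. A part played by acceptor use therefore stays open. Whether SF3B1 mutation by itself could start this response needs replicate cultures given 1 amount of plasmid.

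Many called acceptor pairs had a site with no read in some library. Placement of reads at other acceptors in separately aligned libraries may account for part of them, since the shorter overhang was under 40 nt in 49.1% (44.6 to 53.5) against 7.1% (4.5 to 11.1) of the called pairs read in all 4 libraries. With at least 100 reads at both sites in a library, these percentages were 61.5 (50.4 to 71.6) and 7.8 (3.1 to 18.5). Use of upstream acceptors by mutant SF3B1 may account for another part, since rises made up 56.2% of the calls (52.7 to 59.7) against 45% (42.5 to 47.6) in acceptor pairs at the control distances. These calls were summed over the 3 mutants, so a pair can count up to 3 times and the intervals are too narrow. Both explanations passed the test set for them, but the latter did so by intervals that treat repeated pairs as independent, so its test does not settle it. How much each contributes stays open, and the calls of the 3 mutants share 1 WT library.

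Annotated cassette exons with lower inclusion numbered 255 in K700E, 150 more than in K666T, which had the larger count of the other mutants. Read depth is argued against, as after thinning to 1 depth K700E had 219 such exons against 34 in R625H and 83 in K666T. The amount of plasmid and the mutation cannot be told apart here either, since the larger count was in the library given 2000 ng. An effect of K700E on exon recognition stays open as a hypothesis that these 4 libraries do not test.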

How the results depend on the processing

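The limit to sites read in all 4 libraries, the limit to an annotated downstream acceptor and the alternatives for annotated cassette exons were chosen after the data were examined; all other alternatives were set before. No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out and no other split of the samples was tested. Melanocyte markers had too few genes at a CPM of at least 5 for a median. Where a value below moved, the cause was not tested unless a stricter or looser limit by itself changes how many pairs or genes are counted.

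Acceptor pairs 10 to 30 nt apart had more rises than falls in each mutant under every alternative run. The calls are given as rises against falls in R625H, K666T and K700E. With a limit of 5 points they were 496 against 258, 376 against 278, 368 against 304, and with 20 points 156 against 86, 139 against 104, 133 against 101. With a read minimum of 50 they were 215 against 83, 152 against 85, 142 against 105. Adding multi-mapped reads gave 500 against 321, 389 against 303, 405 against 350. An unannotated upstream and an annotated downstream acceptor gave 138 against 12, 66 against 9, 67 against 13. Both acceptors read in all 4 libraries gave 146 against 35, 103 against 26, 89 against 36, and an annotated downstream acceptor as well 123 against 15, 80 against 7, 67 against 15. The remaining alternatives, with a minimum of 10 reads, a window of 8 to 35 nt, all motifs, an overhang of at least 20 nt or libraries thinned to 1 depth, stayed within 1.5 times the main counts.

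The pooled upstream share in WT, R625H, K666T and K700E was 0.137, 0.329, 0.235 and 0.248% at a minimum of 10 reads, 0.123, 0.302, 0.213 and 0.225% at 50 reads, 0.118, 0.269, 0.198 and 0.206% in a window of 8 to 35 nt, 0.355, 0.604, 0.461 and 0.544% with multi-mapped reads and 0.302, 0.592, 0.471 and 0.48% over pairs read in all 4 libraries. R625H was highest and WT lowest in each of these 5 alternatives. The 6 control classes together gave 361 against 450, 372 against 596, 425 against 971 at 50 reads and 193 against 240, 195 against 402, 288 against 825 with both sites read in all 4 libraries. Between mutants, for R625H over K666T, R625H over K700E and K666T over K700E, calls were 87 against 67, 111 against 59, 90 against 75 at 50 reads, 20 against 17, 40 against 18, 27 against 14 with both acceptors read in all 4 libraries and 15 against 5, 32 against 8, 13 against 2 with an annotated downstream acceptor as well. Libraries thinned to 1 depth left these within 1.5 times. All 12 counts of annotated cassette exons stayed within 1.5 times.

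Genes at least 2-fold higher against lower in R625H, K666T and K700E numbered 190 against 23, 211 against 15, 392 against 135 without a CPM filter and 53 against 2, 49 against 1, 93 against 23 at a CPM of at least 5. Between mutants, in the order above, they numbered 27 against 33, 85 against 178, 64 against 148 without the filter and 2 against 1, 11 against 64, 4 against 68 at a CPM of at least 5. With a prior count of 1, K666T had 2 genes lower than WT, R625H had 8 lower than K666T and K666T had 30 higher than K700E. TMM scaling, size factors and the unstranded column left all these counts within 1.5 times. At a CPM of at least 5, the list of known altered acceptors in K700E came to -0.13 and left the range of random lists, and NF-kB targets in K666T (0.14) and fibroblast markers in R625H (-0.22) fell inside it. The interferon medians at that filter were 2.54, 2.06 and 4.40. The log2 ratio of TSIX in K700E turned from -2.52 to 0.28 with the unstranded column; TSIX overlaps a gene on the opposite strand, whose reads that column adds. Of the alternatives for single named genes, 393 of 416 lay within counting error, and of those for named pairs 213 of 215 kept their call, the exceptions being a DLST pair.

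Depth limits what could be seen. In simulations with counting error only, a share raised by 15 points was called in 86, 88 and 86% of pairs in R625H, K666T and K700E. Some changes near the limit of 10 points were thus missed, and pairs with few reads carry wide intervals.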

Other observations

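The tests of reading frame below were set before their results were seen, and the genes in this part were picked after their values were seen. The acceptor pairs named here were read in all 4 libraries and rose in all 3 mutants. CHTF18, a clamp loader subunit for sister chromatid cohesion, rose from 0.69% in WT to 18.45, 20.4 and 23.47% in R625H, K666T and K700E, and XRCC3, a recombination protein, from 38.62% to 56.14, 63.95 and 54.43% at a 5' UTR exon. SMURF2, a ubiquitin ligase of TGF-beta signalling, rose from 0.75% to 20.38, 11.76 and 17.38%, and the scaffold gene DLG1 from 3.23% to 20.9, 21.78 and 18.97%. The centriole gene CEP135 went from 0.69% to 23.71, 25.49 and 17.83%, and KANSL3, a subunit of a histone acetyltransferase complex, from 0.45% to 21.36, 14.98 and 14.62%. PRPF38A, itself a splicing factor, rose from 4.03% to 16.11, 15.38 and 16.94%, and the mitochondrial valyl-tRNA synthetase gene VARS2 from 0.32% to 18, 14.08 and 10.48%. Inclusion of a cassette exon rose in all 3 mutants in ECT2, a regulator of cytokinesis (21.95% to 40.43, 32.75 and 39.26%), and EIF4A2, a translation initiation helicase (34.76% to 49.4, 51.87 and 45.74%). It fell in FNIP1, a folliculin partner, from 80.95% to 50.49% in K666T and 53.06% in K700E, with 64.37% in R625H.

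The next 4 genes, outside the fixed interferon list, were taken from those at least 2-fold higher in all 3 mutants. DTX3L, a ubiquitin ligase, was higher by log2 2.0, 1.51 and 3.49 in R625H, K666T and K700E, EPSTI1 by 1.97, 1.77 and 3.88, and CMPK2, a mitochondrial nucleotide kinase, by 1.97, 1.67 and 4.55. The chemokine gene CXCL11 had 10 reads in WT and 45, 50 and 246 in the mutants. Of the NF-kB list, 4 cytokine genes lay below the CPM filter: CCL2 with 13 reads in WT against 53, 30 and 45, TNF with 8 against 23, 28 and 34, IL6 with 2 against 10, 6 and 20, and CXCL1 with 25 against 25, 28 and 36. The lambda interferon gene IFNL1 had 4, 3, 5 and 36 reads, and MX1 19, 27, 35 and 75, in WT, R625H, K666T and K700E. DUSP1, a phosphatase of MAP kinases, was higher by 0.71, 0.70 and 0.73, and the stress gene GADD45B by 0.70, 0.59 and 0.82. In K700E, MT-ND6, encoded on the light strand of the mitochondrial genome, was higher by 1.39 (0.01 and 0.00 in R625H and K666T), and the mitochondrial co-chaperonin gene HSPE1 was lower, at -1.26 (-0.01 and -0.14).

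A hypothesis was that upstream acceptors of coding exons that shift the reading frame expose transcripts to decay. The genes tested had a called rise at a coding exon, and those whose pair distance is not a multiple of 3 were compared with random lists of similar expression. An exon counted as coding when any part of it was coding in some transcript. Some acceptors may therefore lie before the start codon, where added bases do not shift the frame. In R625H the median log2 ratio of 62 genes with such a distance was -0.10 (bootstrap 95% interval -0.18 to -0.06), below all random lists, with 47 genes below 0 and 15 above. The 45 genes with a multiple of 3 had -0.02 (-0.05 to 0.01), at percentile 33.46. In K666T the median of 38 genes was -0.13 (-0.20 to -0.03), below all random lists, against 0.00 (-0.04 to 0.05) in 33 genes with a multiple of 3. These intervals overlap slightly. Most of the 38 genes were also among the 62 of R625H, so K666T is no independent repeat. Both results may reflect decay of part of the transcripts. Genes with lower counts included DPH5 (-0.63, -0.55 and -0.45 in R625H, K666T and K700E) and TPP2 (-0.49, -0.48 and -0.27). NSMCE4A was at -0.63 and -0.52 in R625H and K666T. In K700E it was not among the genes with a called rise, yet it had 2817 reads against 5034 in WT. HINT2, also without a call in K700E, had 1523 reads there against 2649 in WT. Lower counts thus also occurred without a called rise. In K700E the median of 25 genes was -0.07 (-0.16 to -0.01), at percentile 5.04, and 28 genes with a multiple of 3 had -0.03. That median lay within the central 95% of random lists, the outcome set beforehand as going against the hypothesis. K700E thus did not meet the prediction. Its interval, which was not part of that rule, excluded 0 and included the medians of the other mutants, so a small effect in K700E is not excluded. Decay itself was not measured, and the gene counts of the 3 mutants share 1 WT library.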
